A study of Arabidopsis thaliana with 16 samples.

How the data were processed

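Transcript levels were measured in roots of 5-day-old Arabidopsis thaliana seedlings on 16 single-channel arrays hybridised with biotin-labelled cRNA. The plants carried LBD16 fused to the glucocorticoid receptor (GR) under the regulatory region of LBD16, in the lbd16-1 lbd18-1 lbd33-1 triple mutant. A GR fusion enters the nucleus once the steroid dexamethasone (DEX) is added. Seedlings were treated for 4 h with or without 2 µM DEX, 10 µM cycloheximide (CHX, an inhibitor of protein synthesis) and 1 µM NAA, a synthetic auxin. All combinations gave 8 groups of 2 arrays each, and the group of each array was taken from its title.

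The deposited table gives 1 intensity per probe set and array on a linear scale, summarised by the authors with Affymetrix Expression Console 1.3. The summary method, the background correction and the scaling are not stated in the sources used here. The 2% trimmed mean over all probe sets was 500 on every array, so the deposited intensities had been scaled array by array. The labels name 2 labelling kits without assigning them to these arrays, so labelling could not be entered as a term. The labels call the arrays of a treatment independent sets, and the deviations of same-numbered arrays from their group means correlated between -0.06 and 0.07 across probe sets over 28 pairs of groups. Arrays with the same number were therefore not treated as pairs.

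Of 22810 probe sets, 64 hybridisation and labelling controls were removed and 22746 were tested without a filter on low values. Intensities were analysed as log2(intensity + 16), which understates the fold changes of weakly expressed genes. Probe sets were named only from the probe annotation and the reference gene table used here: 13513 had exactly 1 gene, 503 had several and 8730 had none listed. The annotation therefore covers part of the array, and a gene absent from the text was not necessarily unchanged. No coordinates are given, since the probe annotation used here names no genome build.

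All 16 arrays entered 1 group-means model in limma 3.58.1 (R 4.3.3), with 8 residual degrees of freedom and moderated variances. All tests were two-sided, p was adjusted by Benjamini-Hochberg over all probe sets of a comparison, and a probe set passed the test at adjusted p under 0.05. Without any change, a share of 0.05 of the 22746 probe sets would have an unadjusted p under 0.05, so such counts do not number responders. There were 12 planned comparisons: DEX against its control in each of the 4 backgrounds, the mean DEX effect over the auxin states with and without CHX, NAA vs mock, NAA+CHX vs CHX, CHX vs mock, and 3 interactions. A 13th contrast, the DEX by NAA interaction in the arrays without CHX, was chosen after seeing the data. Changes are log2 differences of group means with the standard error (SE) of the model, and intensities are means ± SD of 2 arrays. Overlaps between lists of called probe sets stand beside the number that independence would give. Comparisons without a shared array still share the variance estimate of each probe set, so their calls are not fully independent. The p-values measure the spread between these samples, and the number of arrays limits the precision.

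The rule for named genes was set before the data were examined. For the mean DEX effects, NAA vs mock and CHX vs mock it takes the 10 largest rises and 10 largest falls among called probe sets of exactly 1 gene whose arrays do not overlap between the groups compared, and 5 of each for the other comparisons. The condition on overlap was not applied to the interactions. In the other comparisons a called gene named by this part of the rule was therefore higher, or lower, in every array of the treated group, within each auxin state for the mean effects. LBD16, LBD29 and PUCHI are given whatever their values. LBD18 and LBD33 belong to the same rule but have no listed probe set. From each gene list up to 4 called members with the smallest p are named, or up to 2 as values where none passed. Where a gene had several probe sets, the one with the highest mean stands for it. Genes named outside this rule are marked as chosen after their values were seen.

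There were 20 gene lists, fixed before the data were examined, and a gene counted only if its symbol stood in the reference table for its locus. At least 3 genes were measured for 8 lists: early auxin response, auxin response genes named singly, lateral root initiation, stem cell and meristem identity, cell cycle, cell wall loosening, pectin remodelling and rapid stress-responsive transcription. In this order, 12 of 121, 9 of 22, 4 of 29 and 5 of 20 genes were measured. From cell cycle on, it was 3 of 29, 29 of 69, 5 of 34 and 3 of 32. A list test therefore speaks only for the measured genes. The 8 lists were tested with limma's camera with its preset correlation, adjusted over the lists within a comparison, beside camera with an estimated correlation. The estimated form can give a larger p even where that correlation is negative. For lateral root initiation in NAA vs mock it was -0.19, and the unadjusted p was 2.3e-07 preset and 0.00077 estimated. A call lost in the estimated form is therefore not by itself a sign of correlated genes. Of the other 12 lists, LBD family, cytokinin response, ethylene, ribosome biogenesis, cytosolic ribosomal proteins and the markers of green tissue, root hair and endodermis had 1 or 2 measured genes. Fatty acids and suberin, xylem, phloem and root cap had 0. The locus AT4G37295 stood in the lateral root list under a name that the reference table lacks, so it was not counted there. A further 32 families of at least 8 genes with the same letters in their symbols were tested in the same way, a choice made after the coverage of the annotation was seen.

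The calling was tested on simulated data, in which 100 probe sets were shifted by a log2 change of 1 and another 100 by 2. The model recovered 48% and 94% of them in DEX vs mock, 83% and 97% in the mean DEX effect with CHX, and 11% and 67% in the NAA by CHX interaction, with 8, 8 and 4 calls among unshifted probe sets. A simulated list of 12 genes shifted by 0.5 was called, and 0 of 99 unshifted lists were. The simulated noise was independent between probe sets, so false calls of lists with correlated genes were not tested. The alternatives were quantile normalization, median centring, removal of the dimmest 30% of probe sets, an intensity trend with robust variances, only the arrays compared, a replicate block, array weights, pseudocounts of 1 and 64, and each of the 16 arrays left out in turn.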

Results

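Transcript levels were compared across 8 treatments of roots with an LBD16 fusion that DEX activates. LBD16 is a LOB-domain transcription factor of lateral root initiation, and the series was designed to find its primary downstream targets. Each group had 2 arrays, and a treatment was compared with the group that lacked only that treatment, which was mock for DEX, NAA and CHX alone. Median intensity was 150.9 to 174.7 on the 8 arrays without CHX and 179.2 to 189.2 on the 8 arrays with CHX. The 3'-to-5' ratio of the actin control probe sets, a sign of RNA quality, was 17.58 to 26.3 without CHX and 11.07 to 23.46 with it. That of the ubiquitin control was 2.1 to 3.01 and 2.29 to 3.7, and that of the GAPDH control 1.06 to 1.37 and 1.05 to 1.56. CHX separated the arrays along the first principal component, which held 79.7% of the variance, and NAA along the second, with 7.3% of it. The log2 values of the mock arrays differed from each other with an SD of 0.461 across probe sets, against 0.38 to 0.41 in the other groups, and their median intensities were 172.9 and 153.2.

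The LBD16 probe set measured 474.1 ± 42.7 in mock roots and 411.3 ± 36 in DEX-treated roots, and NAA raised it to 5145 ± 102 (n = 2 each). With CHX it measured 893.5 ± 3.25 alone, 857.3 ± 117 with DEX, 1142 ± 21 with NAA and 1432 ± 11.9 with NAA and DEX. LBD16 did not pass the test in any of the 4 DEX comparisons, where its log2 change lay at -0.2, -0.07, -0.55 and 0.32 (SE 0.15 each). The labels do not say whether this probe set reads the fusion, the mutant locus or both. DEX moves the fusion protein and need not change its transcript.

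**Figure D1:**
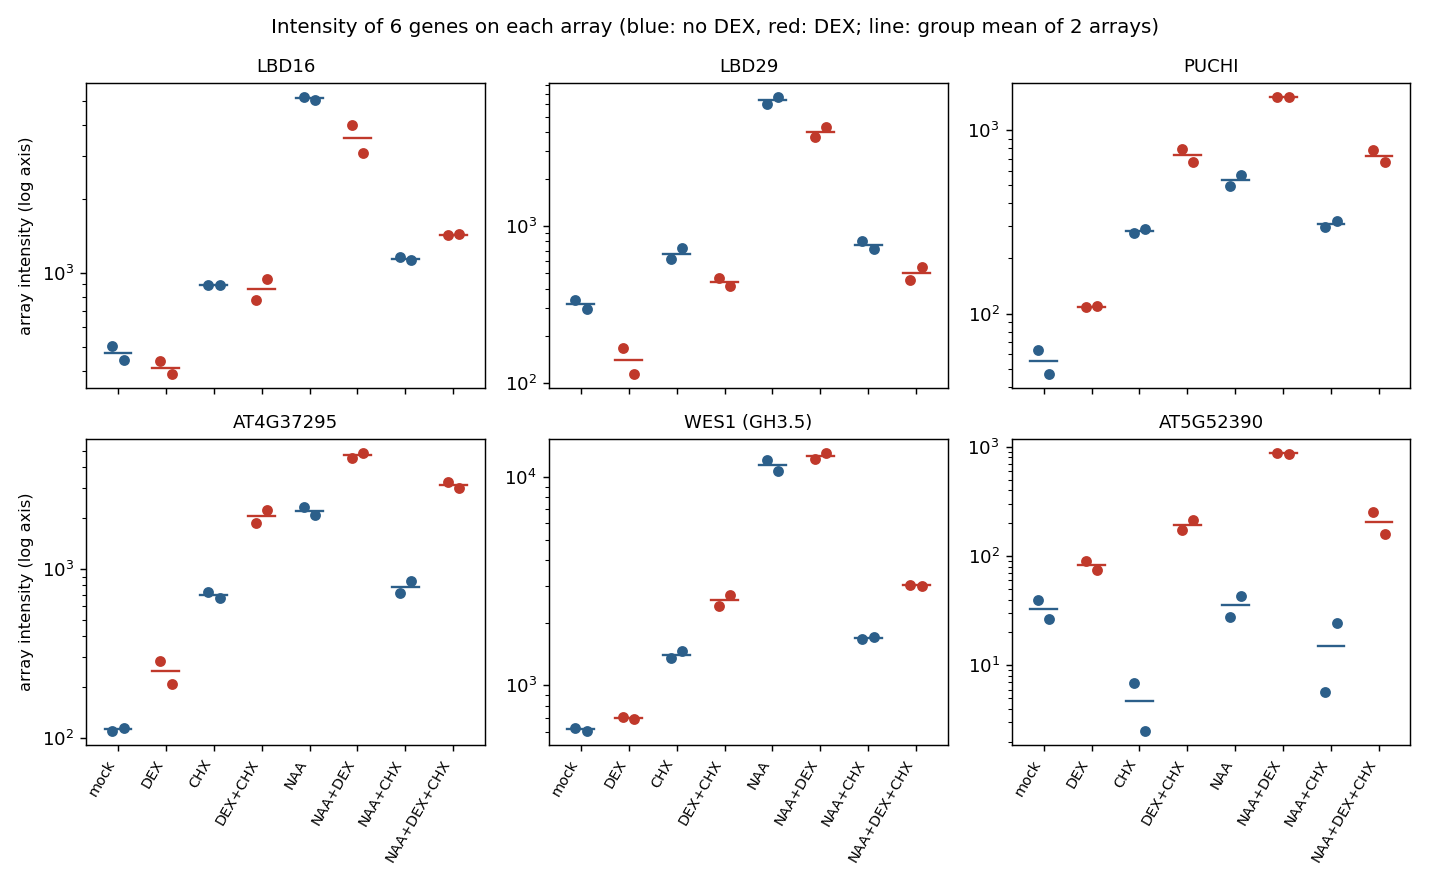
Intensity (log axis) of LBD16, LBD29, PUCHI, AT4G37295, WES1 and AT5G52390 on each of the 16 arrays by treatment, with points for arrays, lines for means of 2 arrays and red for groups with DEX. PUCHI measured 55.12 in mock, 109.3 with DEX, 283.5 with CHX and 733.1 with DEX and CHX, and 533.9 with NAA against 1517 with NAA and DEX.

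The question of primary targets is addressed by DEX under CHX, an inhibitor of protein synthesis. How complete the block was is not measured by these arrays. Averaged over the auxin states, DEX raised AT5G52390 by 3.11 on the log2 scale (8.63-fold, SE 0.21, adjusted p = 6.2e-05), AT1G03820 by 2.7 (6.49-fold, SE 0.14, adjusted p = 8.3e-06) and AT1G64405 by 2.36 (5.15-fold, SE 0.1, adjusted p = 2.4e-06). PUCHI, an AP2/ERF transcription factor of lateral root primordia, rose by 1.25 (2.38-fold, SE 0.11, adjusted p = 0.00039), from 283.5 ± 10.8 to 733.1 ± 85.2 without NAA and from 307.8 ± 15.2 to 722.9 ± 74.6 with it (n = 2 each). SWEET8, a sugar transporter, rose by 1.94 (3.85-fold, SE 0.21), and AT5G17340 and AT4G37295 rose by 1.91 and 1.75. DEP, AT1G30760 and AT1G77280 rose by 1.53, 1.34 and 1.1. WES1 (GH3.5), an enzyme that conjugates auxin to amino acids, rose by 0.84 (SE 0.08, adjusted p = 0.0015), and the expansin genes EXPA20 and EXPA4 rose by 0.86 and 0.76. The falls were smaller: AT5G50130, AT4G07530, AT4G35120 and AT5G05960 changed by -0.96, -0.85, -0.76 and -0.59, and the other 2 probe sets that fell have no listed gene. LBD29 gave -0.59 (SE 0.13, adjusted p = 0.24) and did not pass the test. No roots without the fusion were compared here, so a response to DEX itself is not separated from one to LBD16.

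In all, 33 probe sets passed the test for the mean DEX effect with CHX (27 rose and 6 fell). By state, 12 passed without NAA, all of them rises, against 1123 at an unadjusted p under 0.05, no more than chance gives in 22746 tests. With NAA 25 passed (21 rose and 4 fell), where AT5G60400 and AT1G49200 changed by -1.67 and -1.44 and the other 2 falls have no listed gene. These comparisons share no array, and 10 probe sets rose in both, against 0.0111 under independence (6 and 4 without CHX replicate 1 and replicate 2, 5 and 4 without DEX+CHX replicate 1 and replicate 2, and 6 without NAA+DEX+CHX replicate 1). Among these were AT5G52390, AT1G03820, AT1G64405, AT4G37295, AT5G17340 and PUCHI, with 3.34, 2.66, 1.64, 1.52, 1.47 and 1.32 without NAA and 2.88, 2.74, 3.09, 1.98, 2.35 and 1.19 with it. SWEET8 passed with NAA (2.35, adjusted p = 0.012) and not without it (1.54, adjusted p = 0.2), and its DEX by NAA interaction over the CHX states was 0.59 (adjusted p = 0.7). The 33 became 21 without DEX+CHX replicate 2 and 11 (all rises) in a model of the 8 CHX arrays alone. The number of falls depended on the setting: there were 26 rises and 13 falls without NAA+DEX+CHX replicate 2, 36 and 13 with an intensity trend and robust prior, and 29 and 12 with array weights. The 12 became 5 without CHX replicate 2, and 6 and 4 without DEX+CHX replicate 1 and replicate 2. The 25 became 15 and 12 without NAA+CHX replicate 1 and replicate 2, and 14 without NAA+DEX+CHX replicate 1, and without its replicate 2 they were 15 rises and 12 falls. In models of only the 4 arrays compared, limma called 0 in each, with 1264 and 1496 at an unadjusted p under 0.05.

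No fixed list passed its test for the mean DEX effect with CHX. Of 4 measured lateral root initiation genes 1 rose (PUCHI), 0 fell and 3 were not called (2 called adjusted over the list alone, mean 0.26, adjusted p = 0.086). Of 12 measured early auxin genes 1 rose (WES1), 0 fell and 11 were not called (1 adjusted over the list alone, mean 0.08, adjusted p = 0.086). Of 29 measured cell wall loosening genes, which here are expansins and xyloglucan-modifying XTH enzymes, EXPA4 and EXPA20 rose, 0 fell and 27 were not called (4 adjusted over the list alone, mean -0.02, adjusted p = 0.75). Of 5 stem cell genes 1 rose, PUCHI again, and 4 were not called (1 adjusted over the list alone, mean 0.25, adjusted p = 0.086). Of 5 pectin genes 0 were called (1 adjusted over the list alone), with values of -0.42 for ATPMEPCRB and -0.28 for PME61 (mean -0.18, adjusted p = 0.17). The 9 auxin genes named singly held 1 rise, WES1, and 8 not called (2 adjusted over the list alone, mean 0.06, median -0.03, adjusted p = 0.43). None of the 3 cell cycle genes was called (0 adjusted over the list alone, AUR2 0.2, AUR1 0.05, adjusted p = 0.21), and none of the 3 stress genes was (0 adjusted over the list alone, STZ 0.03, WRKY6 0.02, adjusted p = 0.73).

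Without CHX, DEX again raised AT5G52390, by 2.57 (5.93-fold, SE 0.21, adjusted p = 0.00068), and AT1G05577 by 2.04 (4.11-fold, SE 0.24), AT1G30760 by 1.98 (SE 0.17), AT3G57950 by 1.72 and AT5G17340 by 1.7 as means over the auxin states. PUCHI rose by 1.15 (2.23-fold, SE 0.11, adjusted p = 0.00089). AT5G17350, AT1G29195, AT5G02540 and AT5G11070 rose by 1.3, 1.22, 1.21 and 1.17. The largest falls among named genes were scpl31, a serine carboxypeptidase-like gene, at -1.74 (SE 0.25), AT4G30450 at -1.56 (SE 0.11, adjusted p = 0.00032) and EXLB1, an expansin-like gene, at -1.52 (SE 0.23). AT2G25625, AT1G52560, AT5G43180, AT2G31790, AT1G31050, AT1G21440 and XTH20 changed by -1.48, -1.43, -1.42, -1.4, -1.33, -1.26 and -1.25. LBD29, a LOB-domain gene of lateral root initiation, fell by 0.89 (1.86-fold, SE 0.13, adjusted p = 0.0061). For several of these genes the mean covers unlike auxin states. With NAA, AT1G05577, AT3G57950, AT4G30450 and AT5G43180 gave 3.15, 2.94, -2.91 and -2.51, each beyond its mean. AT1G29195 and LBD29 instead lay beyond their means with DEX alone, at 1.34 and -1.11. AT5G52390 gave 1.01 with DEX alone (adjusted p = 0.47) and 4.12 with NAA. Its DEX by NAA interaction without CHX, a contrast chosen after seeing the data, was 3.11 (SE 0.43, adjusted p = 0.0092).

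The mean DEX effect without CHX passed for 366 probe sets (142 rose and 224 fell). Falls stayed the majority with quantile normalization (165 rises and 191 falls) and not with median centring (166 and 158). The count was 220 and 582 without mock replicate 1 and replicate 2, 190 without DEX replicate 2, 183 and 202 without NAA replicate 1 and replicate 2, and 201 and 230 without NAA+DEX replicate 1 and replicate 2. A model of the 8 arrays without CHX called 91.

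Cell wall genes moved in both directions: of 29 measured, EXPA15, EXPA4 and XTH16 rose by 1.06, 0.62 and 0.58, EXLB1, XTH20, XTH32 and EXLA3 were lower by -1.52, -1.25, -0.71 and -0.67, and 22 were not called (8 called adjusted over the list alone, mean -0.09, adjusted p = 0.71). Of 12 early auxin genes GH3.1 rose by 0.89 (adjusted p = 0.0077), 0 fell and 11 were not called (3 adjusted over the list alone, mean 0.1, adjusted p = 0.16). The homeodomain gene HAT2 fell by 0.5 in the list of 9 singly named auxin genes, where GH3.1 rose, LBD29 fell and 6 were not called (4 adjusted over the list alone, mean -0.12, adjusted p = 0.68). In the lateral root list PUCHI rose and LBD29 fell, with 2 not called (3 adjusted over the list alone, mean 0.04, median -0.05, adjusted p = 0.98). The 3 cell cycle genes had a positive mean of 0.26 (adjusted p = 0.033, and 0.19 with an estimated correlation), with 0 called singly (1 adjusted over the list alone). PRL, a replication helicase subunit, gave 0.38 and AUR1, an Aurora kinase, 0.25, and the list call was lost without mock replicate 2, DEX replicate 2, NAA replicate 1 or NAA+DEX replicate 1. The stem cell list held 1 rise, PUCHI, and 4 not called (1 adjusted over the list alone, adjusted p = 0.3). The pectin list gave 0 calls (0 adjusted over the list alone, adjusted p = 0.68) and the stress list 0 (0 adjusted over the list alone, adjusted p = 0.43).

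Within the arrays without CHX, DEX alone raised AT1G29195 by 1.34 (2.52-fold, SE 0.18, adjusted p = 0.049), from 138 ± 12.6 to 372 ± 18.6, and AT5G67430, AT4G16040, AT1G64405 and AT1G10380 by 1.25, 1.19, 1.03 and 0.97. AT1G77655 fell by 1.52 (SE 0.22), at mean intensities under 50, and AT1G72540 fell by 1.29 (SE 0.13, adjusted p = 0.02). PUCHI gave 0.83 (SE 0.15, adjusted p = 0.12) and LBD29 -1.11 (SE 0.18, adjusted p = 0.083) without passing. DEX vs mock called 12 probe sets (9 rose and 3 fell), against 1675 at an unadjusted p under 0.05. That count was 256 without mock replicate 2, where falls were the majority (61 rises and 195 falls), as they were without DEX replicate 1 (4 and 7) and without mock replicate 1 (1 and 2, 3 in all). It was 0 by limma without DEX replicate 2 (1243 at an unadjusted p under 0.05), with array weights (1162) and with only the 4 arrays compared (1139). It was 6 without either array of DEX+CHX or of NAA+DEX, 3 without either array of NAA+CHX, and 2 without either array of NAA or of NAA+DEX+CHX. All 7 named calls were lost in at least 1 of these settings with an array left out. None of the 8 lists passed its test, with adjusted p of 0.66 for the stem cell list and 1 for the others.

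In roots with NAA, DEX raised AT5G52390 by 4.12 (17.4-fold, SE 0.3, adjusted p = 0.00011), from 35.31 ± 10.9 to 866.7 ± 7.09, and AT1G05577, AT3G57950, AT2G03740 and AT5G17340 by 3.15, 2.94, 2.77 and 2.51. PUCHI rose by 1.48 (2.79-fold, SE 0.15, adjusted p = 0.00035), EXPA15 by 2.1 and EXPA4 by 1.17. Of 29 cell wall genes 3 rose, with XTH16 at 0.87 as the third, 5 fell (EXLB1, XTH20, EXLA3, XTH32 and EXLA1 at -2.19, -1.51, -1.18, -1.04 and -0.67) and 21 were not called (13 called adjusted over the list alone, mean -0.13, adjusted p = 0.33). AT3G62040 fell by 3.13 (8.78-fold, SE 0.25), from 1388 ± 47.2 to 144.1 ± 9.82, and AT4G30450, AT1G49470, AT3G53980 and AT5G43180 changed by -2.91, -2.81, -2.57 and -2.51. PRL was the 1 of 3 cell cycle genes that rose (0.67, SE 0.15, adjusted p = 0.034), 2 were not called (2 called adjusted over the list alone), and the list passed its test (mean 0.54, adjusted p = 0.0048, and 0.082 with an estimated correlation). LBD29 and LBD16 gave -0.68 and -0.55 (adjusted p = 0.087 and 0.088). In all, 667 probe sets passed (277 rose and 390 fell). The count was 290 and 362 without NAA replicate 1 and replicate 2, 352 and 406 without NAA+DEX replicate 1 and replicate 2, and 61 with only the 4 arrays compared.

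The DEX by NAA interaction tests whether these changes differ with auxin, and it passed for 22 probe sets averaged over the CHX states. AT5G17340 responded more with NAA (2.43) than without (1.19), as did EXPA15 (1.05 against 0.11). AT3G62040, AT4G30450 and BCAT4, an enzyme of glucosinolate synthesis, changed by -1.89, -1.71 and -1.35 with NAA and by -0.09, -0.21 and -0.06 without it. AT1G72540 gave 0.6 with NAA and -0.41 without it, an interaction of 1.02 (adjusted p = 0.023), and in the arrays without CHX 1.1 and -1.29, an interaction of 2.39 (adjusted p = 0.0013). PUCHI did not pass this test (0.26, SE 0.15, adjusted p = 0.75). In the arrays without CHX, where the contrast was chosen after seeing the data, 187 probe sets passed (90 higher and 97 lower with NAA, and 224 and 153 without mock replicate 2). The 22 became 51 without mock replicate 2 and 0 by limma without DEX replicate 2 or NAA+DEX replicate 1 (1596 and 1640 at an unadjusted p under 0.05), and 10 of 10 named calls were lost with at least 1 array left out. It was 10 without mock replicate 1, 5 without DEX replicate 1, 6 and 9 without CHX replicate 1 and replicate 2, 2 without either DEX+CHX array, 1 and 2 without NAA replicate 1 and replicate 2, 2 without NAA+DEX replicate 2, 4 without NAA+CHX replicate 2 and 8 without NAA+DEX+CHX replicate 1. The 187 became 90 and 377 without mock replicate 1 and replicate 2, 95 without DEX replicate 2, 89 and 95 without NAA replicate 1 and replicate 2, 91 and 119 without NAA+DEX replicate 1 and replicate 2, and 14 with only the arrays compared.

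Of the 33 probe sets changed by DEX under CHX, 32 had the same sign in the mean DEX effect without CHX. Of these, 16 passed there in the same direction, including AT5G52390, AT1G03820, AT1G64405, AT5G17340, AT4G37295, AT1G30760 and PUCHI. The shared calls were 14 rises and 2 falls, against 0.169 and 0.0591 under independence, and these comparisons share no array. AT5G05960 is 1 of the shared falls and the other has no listed gene. Split by auxin state, 17 of the 33 passed in the same direction in NAA+DEX vs NAA (30 with the same sign, median 0.809 in the called direction). In DEX vs mock 1 passed (29 with the same sign, median 0.148), so most calls without CHX were in roots with NAA. In the other direction, 265 of the 366 probe sets called without CHX had the same sign with CHX and 16 passed. The DEX by CHX interaction tests the difference and passed for 17 probe sets. AT1G03820 and AT1G64405 rose more with CHX (2.7 against 1.04 and 2.36 against 0.84), while AT1G05577, AT5G17350 and EXPA15 rose without CHX by 2.04, 1.3 and 1.06 and gave -0.31, 0.1 and 0.1 with it. PUCHI gave 0.1 (SE 0.15, adjusted p = 0.94).

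The 17 interaction calls became 3 with median centring, 5 with a replicate block and 33 without mock replicate 2. The count was 7 without mock replicate 1, 3 without DEX replicate 2, 2 and 3 without CHX replicate 1 and replicate 2, 2 without either DEX+CHX array, 3 and 2 without NAA replicate 1 and replicate 2, 5 and 2 without NAA+DEX replicate 1 and replicate 2, 8 and 2 without NAA+CHX replicate 1 and replicate 2, and 11 and 2 without NAA+DEX+CHX replicate 1 and replicate 2.

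**Figure D2:**
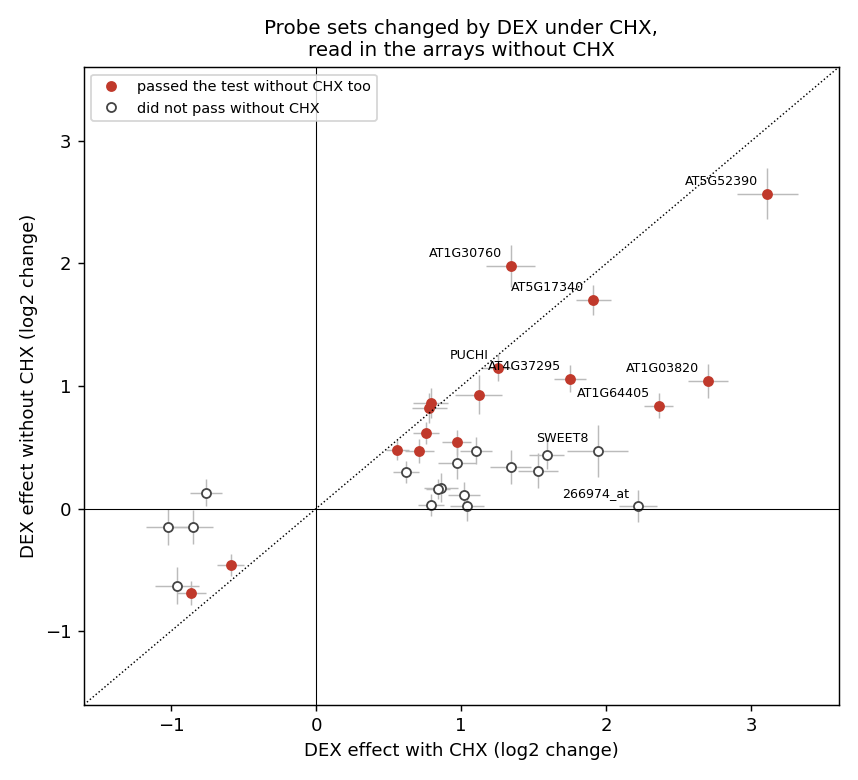
Mean DEX effect with CHX (x axis, log2 change) against that without CHX (y axis, log2 change) for the 33 probe sets called with CHX, with bars of 1 SE and the line of equal change dotted. Filled points mark the 16 that passed without CHX too, and 32 of 33 have the same sign on both axes, with AT5G52390 farthest out at 3.11 and 2.57.

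NAA alone raised the early auxin genes IAA29 by 5.46 (44.15-fold, SE 0.4, adjusted p = 6.6e-06), GH3.3 by 4.84 (28.74-fold, SE 0.23), GH3.1 by 4.41, IAA30 by 4.3 and WES1 by 4.18. LBD29 rose by 4.26 (19.13-fold, SE 0.18, adjusted p = 1.4e-07), from 317.7 ± 32.1 to 6361 ± 481, LBD16 by 3.4 (10.55-fold, SE 0.15) and PUCHI by 2.96 (7.77-fold, SE 0.15). AT2G23060, AT1G73610, AT4G37295 and PR-1-LIKE rose by 4.7, 4.16, 4.11 and 4.04. AT4G25250 fell by 4.75 (26.95-fold, SE 0.36), and AT3G01190, the cell wall gene XTH21, AT2G41810, AT1G19900, AT3G45680, AT5G66815, AT5G04120, GSTU28 (a glutathione transferase) and AT2G43890 changed by -3.6, -3.58, -3.56, -3.51, -3.49, -3.49, -3.36, -3.27 and -3.18. In all, 3042 probe sets passed (1661 rose and 1381 fell). Falls became the majority with median centring (1156 rises and 1640 falls) and quantile normalization (1348 and 1502). The count was 1999 without mock replicate 2, 1510 and 1953 without NAA replicate 1 and replicate 2, and 671 with only the 4 arrays compared.

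Of 12 measured early auxin genes 7 rose, 1 fell (IAA33, -1.25, named after its values were seen) and 4 were not called (8 called adjusted over the list alone), and the list passed its test (mean 1.97, adjusted p = 1.5e-05). Of the 9 auxin genes named singly 8 rose, 0 fell and 1 (CR4, 0.24) was not called (8 adjusted over the list alone, mean 3.34, adjusted p = 8.6e-15). Of 4 lateral root genes LBD16, LBD29 and PUCHI rose, 0 fell and CR4 was not called (3 adjusted over the list alone, mean 2.71, adjusted p = 9.2e-07). These 3 calls held with an estimated correlation (adjusted p = 0.0037, 4e-04 and 0.0031). The lists share members: GH3.1, GH3.3, WES1, IAA20, IAA29 and IAA30 stand in both auxin lists, and CR4 and LBD29 in the singly named and lateral root lists. Of 29 cell wall genes 4 rose, 9 fell and 16 were not called (13 adjusted over the list alone, mean -0.55, adjusted p = 0.0013, and 0.081 with an estimated correlation), with EXPB1, XTH16, XTH21 and XTH32 at -3.1, -3.09, -3.58 and -1.57. The 4 rises, named after their values were seen, were EXPA20, XTH18, EXPA4 and EXLA1 (1.06, 0.9, 0.69 and 0.64). Of 5 stem cell genes only PUCHI rose, 0 fell and 4 were not called (1 adjusted over the list alone, mean 0.85, adjusted p = 0.025, and 0.079 with an estimated correlation). STZ, a zinc-finger repressor, rose by 1.11 as 1 of 3 stress genes, with 2 not called (1 adjusted over the list alone, adjusted p = 0.46). None of the pectin or cell cycle genes was called (0 adjusted over the list alone in each, PME61 0.68 and AUR2 -0.38, adjusted p = 0.49 for each list). Among lists too small to test, RTE1 of the ethylene list rose by 2.04 (SE 0.17) and AT5G14520 of the ribosome biogenesis list by 0.51 (adjusted p = 0.046), while ARR15 and RR16 of the cytokinin list gave -0.76 and -0.74 (adjusted p = 0.34 and 0.15).

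Many of the probe sets that DEX raised under CHX were also raised by NAA alone: 22 of the 27 rises passed in NAA vs mock in the same direction, against 1.97 under independence, and these comparisons share no array. They include AT1G03820 (1.34 with NAA), AT1G64405 (2.46), AT5G17340 (1.68), AT4G37295 (4.11), DEP (1.08), AT1G30760 (3.01), PUCHI (2.96), AT1G77280 (1.99), EXPA20 (1.06), WES1 (4.18) and EXPA4 (0.69). AT5G52390 and SWEET8 did not pass with NAA alone (0.06 and -0.32, adjusted p = 0.94 and 0.55). Of the 6 falls, 2 passed in NAA vs mock in the same direction, AT4G35120 (-0.56) and AT5G05960 (-0.51).

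With CHX present, NAA gave 0.35 for LBD16, 0.18 for LBD29 and 0.11 for PUCHI (adjusted p = 0.38, 0.76 and 0.84), and 1.05, 0.46 and 0.24 for IAA29, GH3.3 and GH3.1, none of which passed. NAA+CHX vs CHX called 38 probe sets (19 rose and 19 fell). AT2G20720 rose by 1.81 (SE 0.19, adjusted p = 0.0066), AT4G21630, AT4G11730, SEC1B and AT3G54520 by 1.62, 1.37, 1.34 and 1.24, while AT4G15390 fell by 1.93 (SE 0.21), and FDH (a formate dehydrogenase), AT1G62510, AT3G48940 and AT2G23400 changed by -1.73, -1.56, -1.44 and -1.28. Of the 12 early auxin genes 0 were called (0 adjusted over the list alone), yet the list passed its test with a mean of 0.39 (adjusted p = 0.0071, and 0.064 with an estimated correlation), a call lost without NAA+CHX replicate 1. The 9 singly named genes also had 0 called (0 adjusted over the list alone), with a mean of 0.31 (adjusted p = 0.019, and 0.098 with an estimated correlation), a call lost without CHX replicate 1 or either NAA+CHX array. The 38 became 0 by limma with only the 4 arrays compared (2627 at an unadjusted p under 0.05), 25 and 3 without CHX replicate 1 and replicate 2, and 18 and 4 without NAA+CHX replicate 1 and replicate 2. It was 181 with dim probe sets removed, 301 with an intensity trend, 100 with array weights, and 14 and 262 with pseudocounts of 1 and 64.

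The NAA by CHX interaction passed for 1025 probe sets (467 positive and 558 negative), and positive values were the majority with quantile normalization (509 and 500) and median centring (524 and 438). GH3.3 gave -4.38 (SE 0.33, adjusted p = 2.5e-05), IAA29 -4.41 (SE 0.57), GH3.1 -4.16, AT2G23060 -4.78, AT1G73610 -4.32, LBD29 -4.08, LBD16 -3.05 and PUCHI -2.85 (SE 0.21, adjusted p = 2.3e-05), while AT3G45680, AT2G41810, AT4G25250, AT1G19900 and XTH21, lowered by NAA alone, gave 4.17, 3.54, 3.45, 3.43 and 3.42. The 1661 probe sets raised by NAA had a median change of 0.82 without CHX and 0.09 with it, and 526 of them passed the interaction test with the opposing sign. The 1381 lowered ones had -0.94 and -0.18, and 417 passed. These medians are read on probe sets chosen in the arrays without CHX, so the first of each is made larger by the choice. The interaction subtracts that same NAA change, so the choice also favours an opposing sign among the 526 and 417. The early auxin, singly named auxin and lateral root lists passed the interaction test with means of -1.58, -3.03 and -2.61 (adjusted p = 8.5e-05, 5.4e-16 and 3.5e-08). These 3 calls held with an estimated correlation (adjusted p = 0.0062, 3e-04 and 0.0015). In the early auxin list 6 were lower, 1 was higher (IAA33, 1.94, named after its values were seen) and 5 were not called (8 adjusted over the list alone), in the singly named list 7 were lower and 2 not called (7 adjusted over the list alone), and in the lateral root list 3 were lower and 1 not called (3 adjusted over the list alone). The cell wall list had a mean of 0.43 with 6 higher, 2 lower (EXPA7 and EXPA4, -0.96 and -0.84, named after their values were seen) and 21 not called (11 adjusted over the list alone, adjusted p = 0.0095, and 0.15 with an estimated correlation). This list call was lost without mock replicate 2 or CHX replicate 1. In the stem cell list PUCHI was lower and 4 were not called (1 adjusted over the list alone, mean -0.76, adjusted p = 0.046, and 0.11 with an estimated correlation), and its call was lost in 14 of 25 settings. The count was 662 and 635 without CHX replicate 1 and replicate 2, 588 without NAA replicate 1, 626 and 507 without NAA+CHX replicate 1 and replicate 2, and 438 with only the 8 arrays compared.

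**Figure D3:**
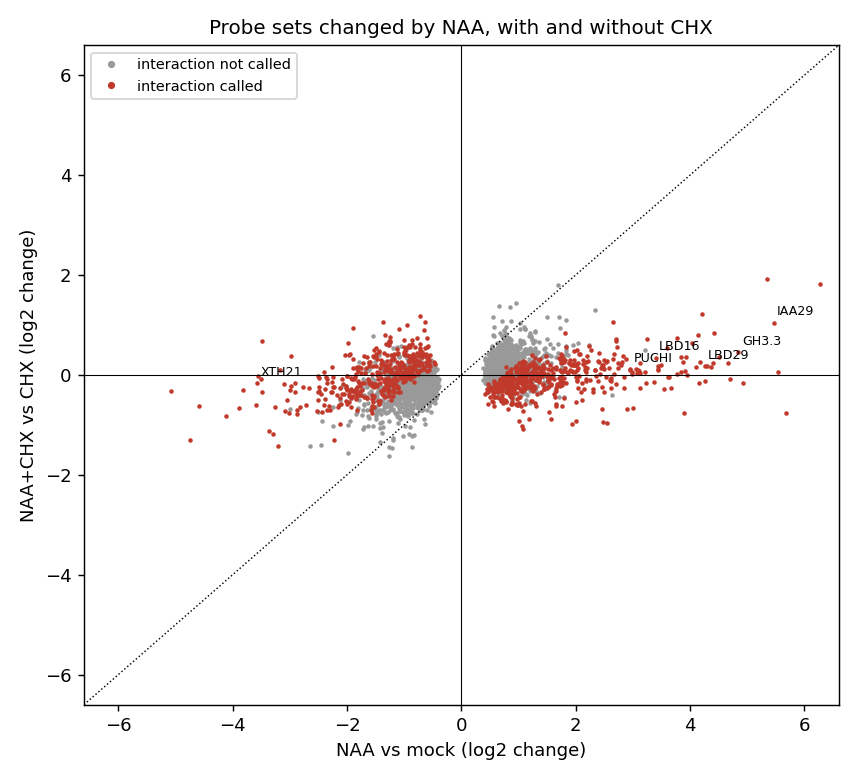
NAA vs mock (x axis, log2 change) against NAA+CHX vs CHX (y axis, log2 change) for the 3042 probe sets called in NAA vs mock, with red points for those whose interaction passed and the line of equal change dotted. IAA29 lies at 5.46 and 1.05, LBD29 at 4.26 and 0.18, and XTH21 at -3.58 and -0.16.

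CHX alone is the background of every CHX group. It raised AT1G22810 by 8.9 (SE 0.23, adjusted p = 2e-10), from 9.361 ± 8.51 to 11730 ± 606, and AT5G52760, AT1G74870, AT2G23270, AT2G37810, AT2G22880, AT2G25735, AT1G10875, AT3G01830 and AT1G51915 by 8.81, 8.8, 8.78, 8.54, 8.5, 8.44, 8.15, 8 and 7.86. All 3 measured genes of rapid stress-responsive transcription rose (3 adjusted over the list alone): STZ by 7.5 (SE 0.23), WRKY53 by 6.92 (SE 0.36) and WRKY6 by 2.76 (SE 0.14). MSRB5, a methionine sulfoxide reductase, fell by 6.65 (100.65-fold, SE 0.19), from 8386 ± 561 to 68.01 ± 14.4, and AT5G57785, AT1G13930 and the defensin-like gene LCR69 changed by -7.52, -6.55 and -5.3. AT1G48750, AT4G11190, AT1G54540, AT2G48130, AT4G30450 and AT2G22590 changed by -6.18, -5.9, -5.78, -5.6, -5.18 and -5.15. PUCHI rose by 2.08 (SE 0.15), LBD29 by 1.04 (SE 0.18) and LBD16 by 0.89 (SE 0.15). In all, 11387 probe sets passed (5241 rose and 6146 fell), 50.1% of those tested. The median change of all probe sets was -0.043, and it was -0.125 with quantile normalization and -0.198 with median centring, so small CHX changes are relative to the scaling.

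Auxin genes rose with CHX as well: of the 9 named singly 8 rose, 0 fell and 1 was not called (8 adjusted over the list alone, mean 2.27, adjusted p = 2e-04, and 0.026 with an estimated correlation), with GH3.1 at 5.29, IAA30 at 4.75 and GH3.3 at 3.51. Of 12 early auxin genes 8 rose, 3 fell and 1 was not called (11 adjusted over the list alone, mean 1.39, adjusted p = 0.036, and 0.11 with an estimated correlation), a call lost with only the arrays compared and without mock replicate 1 or CHX replicate 1. The 3 falls, named after their values were seen, were IAA33, IAA31 and GH3.17 (-1.27, -1.18 and -1.16). The stress list had a mean of 5.73 (adjusted p = 0.0012, and 0.11 with an estimated correlation). Cell wall genes went both ways, with 11 rises, 9 falls and 9 not called (20 adjusted over the list alone, adjusted p = 0.44), among them EXLA3 at 6.79, XTH18 at 4.08 and XTH32 at -3.47. Of 5 pectin genes ATPMEPCRB and PME61 rose by 3.29 and 1.42, PMEPCRF fell by 1.83 and 2 were not called (3 adjusted over the list alone, adjusted p = 0.35). The Aurora kinase genes AUR1 and AUR2 fell (-0.45 and -0.77) and PRL was not called (2 adjusted over the list alone, adjusted p = 0.46). In the lateral root list 3 rose and 1 was not called (3 adjusted over the list alone, mean 1.02, adjusted p = 0.055), and in the stem cell list BBM, an AP2 factor, rose by 1.42 with PUCHI while 3 were not called (2 adjusted over the list alone, adjusted p = 0.29). Among lists too small to test, RR16 fell by 0.83 and AT1G77750, the measured ribosomal protein gene, fell by 0.97.

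Few markers of other cell types could be read. RCA, a photosynthesis gene used as a marker of green tissue, did not pass in NAA vs mock, CHX vs mock or the mean DEX effects with and without CHX, with changes of -0.14, 0.14, -0.1 and -0.24. GSO1, a marker of the endodermis, gave -0.52, 0.45, 0.02 and -0.31 without passing. Of the root hair genes, EXPA18 fell with CHX by 1.18 (adjusted p = 8.3e-05) and EXPA7 gave 0.07.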

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

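The tests of the amount of LBD16 transcript and of more noise under CHX, the DEX by NAA contrast without CHX with its 187 calls, the reassignments for it and for the NAA by CHX interaction, and the ratios on arrays that took no part in the calls, were chosen only after the results were seen. Intervals given here for medians and ratios of medians come from resampling probe sets of the same arrays. They do not measure the spread between arrays.

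By interaction tests the DEX response differed between auxin states for 22 probe sets averaged over CHX states and for 187 in the arrays without CHX, where DEX changed 667 probe sets with NAA and 12 without it (748 and 256 without mock replicate 2, so the size of the gap in counts depends on that array). A deviating mock array as the whole cause is argued against: with either mock array alone as control, the probe sets called with NAA reached at most 0.081 of their change with NAA (95% interval 0.063 to 0.098, and 0.048 with the other array), and 0.034 to 0.062 where that change was read on arrays that took no part in the calls. Array scaling is argued against as well, since quantile normalization left 41.6 times as many calls with NAA as without it (666 against 16). A candidate explanation that stays open is the amount of LBD16 transcript, which NAA raised without CHX: the 33 probe sets changed by DEX under CHX moved further with NAA by a median of 0.538 without CHX (0.323 to 0.714) and 0.082 with CHX (-0.03 to 0.38). Since NAA changed many other transcripts too, this cannot be told apart from other auxin effects, and no measurement of the fusion protein was used here.

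The NAA response differed between CHX states for 1025 probe sets. Array scaling is argued against by 1009 calls with quantile normalization, and more noise under CHX by variances between replicates that were 0.81 of those without CHX (0.65 to 1.03 over the group pairs). Levels already high under CHX may account for part of it: over the probe sets raised by NAA, NAA+DEX stood above DEX+CHX by a median of only 0.38 (0.311 to 0.45). That median is read on arrays with DEX and covers all 1661 raised probe sets, whose median NAA change was 0.82. It is not limited to the 526 that passed the interaction test. Single genes went both ways. CHX alone raised LBD29 by 1.04 and LBD16 by 0.89, against 4.26 and 3.4 with NAA, but raised GH3.1 and IAA30 more than NAA did. A need for new protein in the NAA response stays open as a biological explanation and was not tested separately from the effect of CHX on the starting levels.

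The DEX response differed between CHX states for 17 probe sets, and the mean DEX effect gave mostly rises with CHX (27 of 33) and mostly falls without it (224 of 366), where falls were the majority with NAA (390 of 667) but not with DEX alone (3 of 12). The majority with DEX alone turned to falls when single mock or DEX arrays were left out. Array scaling could account for the majority of falls, since the share of rises was at least 0.848 with CHX and reached 0.512 without CHX under the scaling alternatives (with median centring, against 46.3% with quantile normalization). Low starting levels under CHX are argued against only for the set as a whole. The probe sets that fell without CHX had a median log2 level of 7.48 in the CHX arrays without DEX (7.22 to 8.03), against 8.76 in the mock and NAA arrays. A median does not speak for single genes: CHX alone changed AT4G30450, 1 of the falls, by -5.18, and a low level stays possible there. Falls that need new protein stay open: the probe sets that fell without CHX changed under CHX by a median of -0.116 (-0.146 to -0.091), and those that rose by 0.099. These medians lie between the values that the explanation requires and forbids.

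For the mean DEX effect with CHX, 1 of 34 splits of the 8 arrays, the real one, reached its 20 calls with auxin as a term, and the highest other split gave 3. Chance is argued against for these 20 calls as a count. The 33 calls of the model of all arrays, and single probe sets, were not tested in this way. For the effect without CHX, 1 of 34 reached its 2 calls and the highest other gave 0, counts too near 0 to speak for the 366 calls of the model of all arrays. For the DEX by CHX interaction 10 of 100 reassignments reached 17 calls (highest other 237), and for the DEX by NAA interaction 7 of 100 reached 22 (highest other 155). The other 9 and 6 reassignments with as many calls all left NAA apart from NAA+DEX, which points to a structure of the arrays: the difference between these groups then enters the contrast, so these counts do not settle whether chance can be excluded. Reassignments without that feature gave at most 2 and 4 calls. The 237 calls came from a reassignment that kept the arrays of every group together and only exchanged labels. That count therefore reads treatment effects and not chance. For the NAA by CHX interaction (1025 calls, highest other 2278, 2 of 18 with as many) and the DEX by NAA interaction without CHX (187, highest other 366, 5 of 18), the 18 reassignments are too few for a share under 0.05. Both sets also include an exchange of the labels within a single state. That exchange turns the interaction into a mean treatment effect, and the mean DEX effect without CHX has 366 calls. These highest counts therefore do not show what chance gives.

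Named genes whose DEX response differed with CHX are given as the interaction on the log2 scale. AT1G03820, AT1G64405, AT1G21440, AT4G03740 and AT4G30450 had 1.66, 1.53, 1.23, 1.2 and 1.19. AT1G05577, AT1G48100, AT5G17350, EXPA15 and AT1G10380 had -2.35, -1.35, -1.2, -0.96 and -0.94.

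For the difference of the DEX response with NAA, AT5G17340, AT3G57780, AT1G72540, EXPA15 and AT2G43860 had 1.24, 1.23, 1.02, 0.94 and 0.89. AT3G62040, AT4G30450, BCAT4, AT5G01210 and tny, an AP2/ERF gene, had -1.8, -1.5, -1.28, -1.15 and -0.98.

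For the difference of the NAA response with CHX, AT3G45680, AT2G41810, AT4G25250, AT1G19900 and XTH21 had 4.17, 3.54, 3.45, 3.43 and 3.42. AT2G23060, IAA29, GH3.3, AT1G73610 and GH3.1 had -4.78, -4.41, -4.38, -4.32 and -4.16, and LBD29, LBD16 and PUCHI had -4.08, -3.05 and -2.85.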

How the results depend on the processing

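The DEX by NAA contrast without CHX was chosen only after its result was seen, and all other tests here were planned. Counts are calls at adjusted p under 0.05, and the cause of a change was not tested except where fewer arrays or probe sets were used. The CHX vs mock count (11387) and the 17 list calls stayed within 1.5 times their value in all 25 settings.

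With only the arrays compared, which leaves fewer degrees of freedom, the counts became 0 for DEX vs mock (12), DEX+CHX vs CHX (12), NAA+DEX+CHX vs NAA+CHX (25), NAA+CHX vs CHX (38) and the calls shared under CHX (10), 61 for NAA+DEX vs NAA (667), 11 for the mean DEX effect with CHX (33), 91 for that without (366), 671 for NAA vs mock (3042), 438 for NAA by CHX (1025) and 14 for DEX by NAA without CHX (187). The limma counts of 0 stood beside 1139, 1264, 1496 and 2627 at an unadjusted p under 0.05, where chance alone puts a share of 0.05 of all probe sets. The DEX interactions averaged over all groups already use every array, so this setting gave no value for them. An intensity trend gave 23 for DEX vs mock, 1100 for NAA+DEX vs NAA, 620 for the DEX effect without CHX, 301 for NAA+CHX vs CHX, 97 for DEX by CHX (17), 106 for DEX by NAA (22), 1606 for NAA by CHX, 328 for DEX by NAA without CHX and 16 shared calls. A pseudocount of 64 gave 1053 for NAA+DEX vs NAA, 589 for the DEX effect without CHX, 262 for NAA+CHX vs CHX, 101 for DEX by CHX, 95 for DEX by NAA, 1549 for NAA by CHX and 349 for DEX by NAA without CHX. A pseudocount of 1 gave 4 for DEX vs mock, 14 for NAA+CHX vs CHX, 6 for DEX by CHX and 7 for DEX by NAA. Removing dim probe sets gave 181 for NAA+CHX vs CHX, 69 for DEX by CHX, 74 for DEX by NAA and 319 for DEX by NAA without CHX. Array weights gave 0 for DEX vs mock (1162 at an unadjusted p under 0.05) and 100 for NAA+CHX vs CHX, a replicate block gave 3 for DEX vs mock and 5 for DEX by CHX, and median centring gave 3 for DEX by CHX. The array weights were equal within each group (0.62 for both mock arrays), so they reweighted groups and could not single out an array.

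With each array left out in turn, where the lone array of a group is assumed to vary like the other groups, the counts ranged from 0 to 256 for DEX vs mock, 4 to 15 for DEX+CHX vs CHX, 290 to 748 for NAA+DEX vs NAA, 12 to 27 for NAA+DEX+CHX vs NAA+CHX, 21 to 39 for the DEX effect with CHX, 183 to 582 for that without, 1510 to 2978 for NAA vs mock, 3 to 51 for NAA+CHX vs CHX, 9938 to 11335 for CHX vs mock, 2 to 33 for DEX by CHX, 0 to 51 for DEX by NAA, 507 to 1005 for NAA by CHX, 89 to 377 for DEX by NAA without CHX, 4 to 10 for the shared calls and 14 to 20 for the list calls. Of 253 called values of named genes, 0 reversed, 78 were lost with at least 1 array left out and 109 in at least 1 of the 9 other alternatives, 86 of them with only the arrays compared. Another 6 values, called neither in the setting nor as reported, changed sign. The named calls lost with an array left out were 7 of 7 for DEX vs mock, 4 of 7 for DEX+CHX vs CHX, 5 of 9 for NAA+DEX+CHX vs NAA+CHX, 4 of 22 for NAA+DEX vs NAA, 6 of 17 and 4 of 28 for the DEX effects with and without CHX, 7 of 41 for NAA vs mock, 9 of 10 for NAA+CHX vs CHX, 8 of 66 for CHX vs mock, 9 of 10 for DEX by CHX, 10 of 10 for DEX by NAA and 5 of 26 for NAA by CHX. Weak signal limits the folds of genes under an intensity of 50, 28.4% to 32.8% of probe sets per array.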

Other observations

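The name families were chosen as a test only after the coverage of the annotation was seen, and the hypothesis on NAA-responsive genes was noticed in these data but its test was set before its result was seen.

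Some name families passed the test with the preset correlation for CHX or NAA, and none of these calls held with an estimated one. Of 9 measured PUB genes, U-box ubiquitin ligases, 6 rose with CHX, 0 fell and 3 were not called (mean 2.31, adjusted p = 0.005, and 0.27 with an estimated correlation), with PUB24 at 5.25, PUB23 at 4.27, PUB26 at 3.73, PUB22 at 3.17, PUB25 at 3.13 and PUB19 at 1.47. Of 14 SWEET sugar transporter genes 4 fell with NAA, 0 rose and 10 were not called (mean -0.39, adjusted p = 0.021, and 0.22 with an estimated correlation), with SWEET14 at -1.59, SWEET13 at -1.35, SWEET17 at -0.84 and SWEET16 at -0.77. Of 9 XTH genes XTH21, XTH16, XTH33 and XTH32 fell with NAA (-3.58, -3.09, -1.7 and -1.57), XTH18 rose by 0.9 and 4 were not called (mean -1.03, adjusted p = 0.0035, and 0.26 with an estimated correlation). Of 22 TBL genes 6 fell with NAA, 1 rose (TBL42, 0.95) and 15 were not called (mean -0.24, adjusted p = 0.018, and 0.34 with an estimated correlation), with TBL21 at -1.3 and TBL38 at -1.27. Of 11 RALFL genes, which encode small secreted peptides, 3 fell with NAA, 0 rose and 8 were not called (mean -0.35, adjusted p = 0.018, and 0.22 with an estimated correlation), with RALFL24 at -0.65. Of 11 PRA genes 3 fell with NAA, 0 rose and 8 were not called (mean -0.28, adjusted p = 0.018, and 0.26 with an estimated correlation). In the NAA by CHX interaction the SWEET and XTH families had means of 0.46 and 0.86 (adjusted p = 0.035 and 0.0036, and 0.37 and 0.38 with an estimated correlation). The directions held under quantile normalization and median centring.

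For DEX the calls with the preset correlation rested on few genes or none. Of 10 EXPA expansin genes EXPA15 and EXPA4 rose without CHX by 1.06 and 0.62, 0 fell and 8 were not called (mean 0.24, adjusted p = 0.0046, and 0.27 with an estimated correlation). In roots with NAA these genes rose by 2.1 and 1.17 (family mean 0.39, adjusted p = 0.033, 0.052 with median centring and 0.36 with an estimated correlation). Of 47 UGT glycosyltransferase genes UGT74B1, an enzyme of glucosinolate synthesis, UGT76C2 and UGT71C5 fell with DEX in roots with NAA (-1.2, -1.12 and -0.69), UGT84A4 rose by 0.68 and 43 were not called (mean -0.29, adjusted p = 0.02, and 0.31 with an estimated correlation). With CHX the mean DEX effect was 0.18 for EXPA, with EXPA4 and EXPA20 called, -0.23 for XTH and -0.22 for 8 RPS genes, with 0 called in both (adjusted p = 0.02, 0.0097 and 0.029, and 0.59 each with an estimated correlation). The RPS family was formed from symbols alone and shares no measured gene with the list of cytosolic ribosomal proteins. In NAA+DEX+CHX vs NAA+CHX, RPS and XTH had means of -0.41 and -0.25 with 0 called (adjusted p = 0.004 and 0.046, and 0.49 each with an estimated correlation). In the DEX by CHX interaction 8 LCR genes had a mean of 0.39 with 0 called (adjusted p = 0.011, and 0.19 with an estimated correlation). No family call among the 32 families tested held with an estimated correlation, which by itself does not show that correlated genes made the calls. EXPA15 measured 1852 ± 72.3 in mock, 846.4 ± 66.7 with NAA and 3677 ± 166 with NAA and DEX (n = 2 each).

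A hypothesis was that DEX moves NAA-responsive genes back towards mock, since LBD29, raised by NAA, was lower with DEX, and EXPA15, lowered by NAA, was higher with it. With separate NAA arrays for the choice and the reading, the covariance of the DEX change with the NAA change was 0.0176 (0.015 and 0.0202 in the 2 ways), which argues against it over all probe sets, since the hypothesis needs a negative value. Of the probe sets called for NAA without the array used, 722 of 1510 (47.8%) and 844 of 1953 (43.2%) moved the other way with DEX. These were 415 of 781 and 482 of 1042 of the raised ones, with medians of -0.033 and 0.033 that differ in sign, so the raised ones taken alone stay open. Of the lowered ones they were 307 of 729 and 362 of 911.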
